A study of Ovis aries with 9 samples.

How the data were processed

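RNA from the longissimus dorsi of Chinese merino fetuses at gestation days 85, 105 and 135 was sequenced, with 3 libraries per day grouped by the titles and the age given in the labels. Per the labels' protocols, total RNA was extracted with Trizol, and an mRNA kit and a small RNA kit were used for libraries; the design text names 2 Illumina HiSeq models, without saying which library ran on which, so a batch could not be tested. The FPKM values (fragments scaled by transcript length and by the number of mapped fragments) were deposited by the authors as a table with a column per library, per the file headers. Per the submitters' processing notes, cutadapt, Bowtie2 and TopHat2 were used, without versions or order; the genome build, the assembler and the counting are not given in the sources used here, and no coordinates are printed. Many locus identifiers have the form that StringTie gives to assembled loci, and 211 loci join several gene names, so reads of near-identical neighbours such as the myosin heavy chains cannot be divided between them.

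Depth in reads is unknown, since FPKM holds no counts, and no count test was run. The table has 22605 loci, 16537 with a gene symbol, 5632 named only by a locus number and 436 without a name. Of the loci with a gene symbol, 494 took one from a RefSeq gene table of the ARS-UI_Ramb_v3.0 assembly, used for names alone. Between 2767 and 3249 loci were listed at 0 per library. At 30 loci a library was at 0 although the median over all libraries was 20 FPKM or more, so a 0 may be a failed estimate. Values by library are given for some of the named loci at 0. Of the tested loci 952 hold no reference transcript.

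Loci with FPKM of at least 1 in at least 3 libraries (13086) were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend), all 9 libraries in a single fit without a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were D105 against D85, D135 against D105, D135 against D85, D105 against the mean of D85 and D135, and any day by the moderated F test. Gene lists fixed before the data were examined (44 lists, 944 of 1011 entries matched, 18 by product description) were tested with camera, two-sided, with a preset correlation of 0.01 and at least 5 tested members, which left 40 lists; the estimated correlation was an alternative. Lists hold genes that other lists share, and counts adjusted over the list alone use only its members. On simulated data for D105 against D85 (13086 genes drawn independently), limma recovered 79% of 100 genes changed by a log2 of 1. It recovered 90% of 100 changed by 2, with 5 calls among unchanged genes. The changes were put only into genes with a mean log2(FPKM + 1) above 2, so these shares do not cover lower genes. Camera called 2 of 2 shifted lists and 0 of the unshifted. The simulated lists held uncorrelated genes, so this does not show how often camera wrongly calls lists of correlated genes.

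Genes were named by a rule set before the data were examined. It took the 8 largest called changes in each direction per comparison (adjusted p under 0.05, mean of at least 1 FPKM in the higher day, a symbol, libraries not overlapping), up to 4 called members with the largest change of each list described (or the 2 with the highest mean), any member of 5 muscle and growth lists, the 5 largest in each direction for D105 against the mean of the other days, and the 5 highest loci per day. COL1A1 and COL1A2 were named after their values were seen. Alternatives changed the pseudocount, the filter, the scaling (median of ratios, quantiles, totals without the top 50 loci), the variance model, library weights, the libraries and loci fitted, a replicate block and each library in turn. Loci without a reference transcript, loci with a doubtful 0 (median of the others 5 FPKM or more), members matched by description, and an estimated correlation with median-of-ratios scaling were added as alternatives after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.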

Results

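Gene expression in the longissimus dorsi, the long muscle along the back, was measured by RNA sequencing in Chinese merino sheep fetuses at gestation days 85, 105 and 135 (D85, D105 and D135), with 3 libraries per day. The values were FPKM for 22605 loci, of which 13086 were tested. The labels do not say that the libraries of a day came from separate fetuses, so the p-values measure the spread between these libraries, which may be technical. The number of reads per library is unknown because the table holds no counts, and the total ranged from 395797 to 489270 FPKM. From 76 to 107 loci with low values put the depth at 0.993 to 1.20 times that of D85 replicate 1, with the D135 libraries deepest. Yet D135 replicates 1, 2 and 3 had the most loci listed at 0 (3196, 3249 and 3225). They also had the fewest loci at FPKM 1 or more (11497, 11283 and 11346). The 4 loci of highest mean FPKM among those without a gene name took 49.4% to 60.0% of the total. Among named genes, MYLPF, the fast regulatory myosin light chain, was highest at D85 and D105 with 3201 ± 675 and 3575 ± 1419 FPKM (SD, n = 3). ACTA1, skeletal alpha-actin, was highest at D135 with 5292 ± 1153 FPKM.

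Libraries of the same day correlated across the tested loci with a mean Pearson r of 0.907 ± 0.0144 (SD over 9 pairs). The mean r was 0.890 between D85 and D105, 0.864 between D105 and D135 and 0.832 between D85 and D135. Genes are not independent replicates, and no test was made of these values. D105 replicate 2 stood apart on the second principal component, and in that library COL1A1, a chain of type I collagen, was at 1889 FPKM against 403 and 419 in the other D105 libraries. The median log2 change of all tested loci was -0.02 for D105 against D85, -0.33 for D135 against D105 and -0.35 for D135 against D85, so medians of lists are given relative to it.

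**Figure D1:**
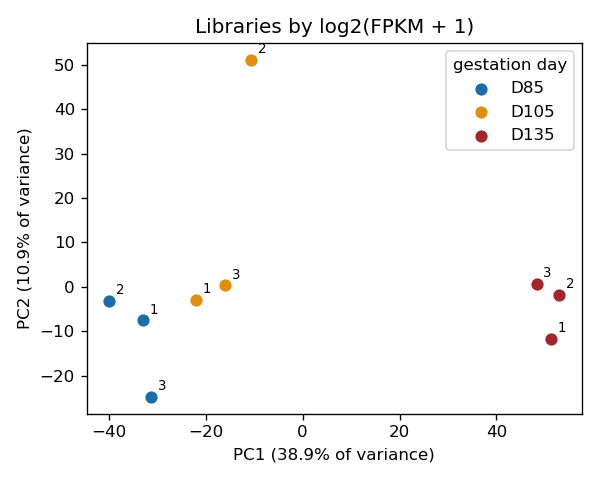
Principal components of log2(FPKM + 1) over the tested loci, with each point a library numbered by replicate and colored by gestation day. The horizontal axis (38.9% of the variance) places the D135 libraries on the right of the D85 and D105 libraries, and the vertical axis (10.9%) sets D105 replicate 2 above the other libraries.

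The comparison of D105 with D85 asks what changed in the muscle over the earlier interval. EEF1A2 (MSTRG.6518), the translation elongation factor isoform of mature muscle and neurons, rose from 5.61 ± 2.85 to 112 ± 48.5 FPKM (log2 change 4.11 ± 0.36 SE, adjusted p = 0.00768; SD, n = 3). ACTN3 (MSTRG.9311), the Z-disc alpha-actinin of fast fibres, rose from 5.84 ± 1.43 to 67.6 ± 25.4 FPKM (log2 change 3.28 ± 0.29 SE, adjusted p = 0.00768). RPL3L, the striated-muscle paralog of ribosomal protein L3, rose from 2.63 ± 0.927 to 10.6 ± 1.34 FPKM, and RGS5, a pericyte marker, from 3.11 ± 0.0747 to 17.3 ± 5.47 FPKM. COL15A1, a basement membrane collagen, rose from 77.3 ± 8.85 to 169 ± 5.36 FPKM (adjusted p = 0.0155), and the kinase gene UHMK1 from 2.20 ± 0.400 to 8.28 ± 0.105 FPKM (adjusted p = 0.00195). All log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes. RMI2, of the Bloom helicase complex, and KLHL33 rose by log2 changes of 1.53 and 1.37. Those that fell were FAM122B (-1.39), CNTN3, a contactin (-1.05), PRSS23, a serine protease (-1.01), STK26, a kinase (-0.97), and KCNN1, a calcium-activated potassium channel (-0.86, with an adjusted p of 0.0809 after median-of-ratios scaling).

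Of 16 endothelial markers tested in this comparison, 1 rose, 0 fell and 15 did not pass, against 10 that rose and 0 that fell adjusted over the list alone. The endothelial list had a median 0.56 above that of all loci (camera adjusted p = 6.46e-13, and adjusted p = 0.173 with an estimated correlation). EGFL7, secreted by endothelial cells, rose from 13.9 ± 1.0 to 25.3 ± 1.28 FPKM (SD, n = 3). Of 12 adipocyte markers, 0 rose, 0 fell and 12 did not pass, against 1 that rose and 0 that fell adjusted over the list alone. The adipocyte list had a median 0.55 above that of all loci (camera adjusted p = 0.000796, and adjusted p = 0.406 with an estimated correlation). Camera's direction was also up for the other lists of non-muscle cells that passed and for the interferon list. Of 12 leukocyte markers, 0 rose, 0 fell and 12 did not pass, against 1 that rose and 0 that fell adjusted over the list alone. The leukocyte list had a median 0.38 above that of all loci (camera adjusted p = 0.0143, and adjusted p = 0.406 with an estimated correlation). Of 15 fibroadipogenic and fibroblast markers, 0 rose, 0 fell and 15 did not pass, against 1 that rose and 0 that fell adjusted over the list alone. The fibroadipogenic and fibroblast list had a median 0.24 above that of all loci (camera adjusted p = 0.0310, and adjusted p = 0.458 with an estimated correlation). Of 14 smooth muscle and pericyte markers, 1 rose, 0 fell and 13 did not pass, against 2 that rose and 0 that fell adjusted over the list alone. The smooth muscle and pericyte list had a median 0.16 above that of all loci (camera adjusted p = 0.0406, and adjusted p = 0.406 with an estimated correlation). Of 17 genes of interferon response and antigen presentation, 0 rose, 0 fell and 17 did not pass, against 0 that rose and 0 that fell adjusted over the list alone. The interferon and antigen presentation list had a median 0.42 above that of all loci (camera adjusted p = 0.00262, and adjusted p = 0.458 with an estimated correlation). Tendon, cartilage and bone, Schwann and nerve, and epidermis lists did not pass (camera adjusted p = 0.860, 0.342, 0.175 and 0.806). With a library left out, the camera call was lost for the adipocyte (adjusted p = 0.148 without D105 replicate 2), leukocyte (adjusted p = 0.175 without D85 replicate 2 and 0.186 without D105 replicate 2), fibroadipogenic (adjusted p = 0.175 without D85 replicate 2, 0.117 without D85 replicate 3 and 0.404 without D105 replicate 2), smooth muscle (in 6 fits, up to adjusted p = 0.166 without D105 replicate 1) and interferon lists (adjusted p = 0.180 without D105 replicate 2). Without D105 replicate 2, which stood apart, the medians of the adipocyte, leukocyte, fibroadipogenic and interferon lists relative to all loci were 0.20, 0.11, -0.02 and 0.25. LPL, lipoprotein lipase, was at 2.95, 41.1 and 4.79 FPKM in D105 replicates 1, 2 and 3. In the same libraries FMOD, a tendon marker, was at 7.32, 164 and 10.1 FPKM and COL2A1, cartilage collagen, at 1.07, 67.8 and 1.88 FPKM.

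Of 13 adult fast fibre isoforms, 1 rose, 0 fell and 12 did not pass, against 5 that rose and 0 that fell adjusted over the list alone. The adult fast list had a median 0.43 above that of all loci (camera adjusted p = 1.29e-07, and adjusted p = 0.221 with an estimated correlation). Of 17 imprinted genes, 0 rose, 0 fell and 17 did not pass, against 0 that rose and 2 that fell adjusted over the list alone. The imprinted list had a median of -0.39 relative to all loci (camera adjusted p = 0.00679, and adjusted p = 0.221 with an estimated correlation). Of 44 cell cycle genes, 0 rose, 0 fell and 44 did not pass, against 0 that rose and 0 that fell adjusted over the list alone. The cell cycle list had a median of -0.21 relative to all loci (camera adjusted p = 1.09e-06, and adjusted p = 0.406 with an estimated correlation). TOP2A and MCM7, the cell cycle members with the highest means, were at 26.9 ± 2.89 and 21.7 ± 0.786 FPKM at D85. At D105 they were at 24.1 ± 1.48 and 19.4 ± 0.347 FPKM (SD, n = 3). Of 10 embryonic and neonatal muscle isoforms, 0 rose, 0 fell and 10 did not pass, against 0 that rose and 0 that fell adjusted over the list alone. The embryonic and neonatal list had a median of -0.64 relative to all loci (camera adjusted p = 0.0341, and adjusted p = 0.406 with an estimated correlation). That call was lost with a library left out (adjusted p = 0.112 without D85 replicate 3 and 0.248 without D105 replicate 2). Without D105 replicate 2 the median of this list was -0.41 relative to all loci. MYH8, neonatal myosin, was at 1438 ± 156 and 1642 ± 340.3 FPKM at D85 and D105. ACTC1, cardiac actin, was at 1418 ± 364 and 723 ± 256 FPKM.

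In all, limma called 26 of 13086 loci between D105 and D85, 19 higher and 7 lower, with 1611 loci at an unadjusted p under 0.05. Camera called 25 of 40 lists with the preset correlation and 0 with an estimated correlation. The called lists included glucocorticoid-responsive genes, glycolysis and the thyroid axis (direction up, camera adjusted p = 0.000543, 0.000796 and 0.000796). Fatty acid, oxidative phosphorylation and tricarboxylic acid lists were up too (camera adjusted p = 0.00256, 0.00791 and 0.0251). Ribosomal proteins were down (camera adjusted p = 0.000599). In each of these lists 0 members passed over all loci. The oxidative phosphorylation call was lost without D85 replicate 2 (camera adjusted p = 0.0928) and without D105 replicate 1 (camera adjusted p = 0.109). The tricarboxylic acid call was lost without D85 replicate 3 (camera adjusted p = 0.1105) and without D105 replicate 1 (camera adjusted p = 0.101). The count of lists fell to 15 without D85 replicate 2 or D105 replicate 2 and to 16 without D85 replicate 3. The split of loci turned to 10 higher and 18 lower without D105 replicate 1, to 10 higher and 12 lower without D105 replicate 2 and to 21 higher and 24 lower without a filter on low values. The count of loci fell to 14 without D135 replicate 2, and to 16 without D85 replicate 2 or D85 replicate 3. EEF1A2, ACTN3, RGS5 and UHMK1 kept their calls with each of the 9 libraries left out. Of the other genes that rose, calls were lost in some of those fits for RPL3L (in 7 fits, up to adjusted p = 0.0964 without D85 replicate 2), RMI2 (in 5 fits, up to adjusted p = 0.0935 without D85 replicate 1), KLHL33 (in 6 fits, up to adjusted p = 0.0685 without D105 replicate 3), COL15A1 (adjusted p = 0.0567 without D85 replicate 3) and EGFL7 (in 7 fits, up to adjusted p = 0.106 without D85 replicate 1). Of the genes that fell, calls were lost for FAM122B (adjusted p = 0.0567 without D85 replicate 3, 0.0621 without D85 replicate 2), CNTN3 (in 7 fits, up to adjusted p = 0.0945 without D85 replicate 2), PRSS23 (in 9 fits, up to adjusted p = 0.158 without D85 replicate 1), STK26 (in 6 fits, up to adjusted p = 0.0945 without D85 replicate 2) and KCNN1 (in 9 fits, up to adjusted p = 0.139 without D105 replicate 3).

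Between D105 and D135 most slow contractile isoforms rose, and more adult fast isoforms rose than fell. More embryonic and neonatal isoforms fell than rose. Of 14 slow fibre isoforms, 11 rose, 0 fell and 3 did not pass, against 12 that rose and 0 that fell adjusted over the list alone. The slow list had a median 1.90 above that of all loci (camera adjusted p = 5.08e-16, and adjusted p = 0.0364 with an estimated correlation, or 0.0739 with that and median-of-ratios scaling together). TNNT1, slow troponin T, rose from 71.7 ± 24.2 to 646 ± 275 FPKM (log2 change 3.11 ± 0.36 SE, adjusted p = 0.00125; SD, n = 3). MYL2, the slow and ventricular regulatory light chain, rose from 371 ± 129 to 2821 ± 1041 FPKM (log2 change 2.91 ± 0.38 SE, adjusted p = 0.00186). TPM3, slow tropomyosin, rose from 84.6 ± 43.7 to 541 ± 200.5 FPKM. Of 13 adult fast fibre isoforms, 7 rose, 1 fell and 5 did not pass, against 9 that rose and 1 that fell adjusted over the list alone (9 rose and 1 fell after median-of-ratios scaling, 5 and 2 after quantile normalization). The adult fast list had a median 1.37 above that of all loci (camera adjusted p = 3.73e-11, and adjusted p = 0.0417 with an estimated correlation, or 0.149 with that and median-of-ratios scaling together). The joined locus of MYH4, MYH2 and MYH1, the adult fast myosins, rose from 139 ± 61.0 to 1000.2 ± 344 FPKM (log2 change 2.87 ± 0.35 SE, adjusted p = 0.00150). How its reads divide between these near-identical genes is uncertain. CASQ1, fast calsequestrin, rose from 267 ± 51.2 to 733 ± 98.6 FPKM and ACTN3 from 67.6 ± 25.4 to 193 ± 48.9 FPKM. PVALB, parvalbumin, was the member that fell, from 2.68 ± 1.69 to 0.225 ± 0.116 FPKM.

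Among 10 embryonic and neonatal isoforms compared between D105 and D135, 1 rose, 7 fell and 2 did not pass, against 1 that rose and 7 that fell adjusted over the list alone (1 rose and 3 fell after median-of-ratios scaling, 1 and 3 after quantile normalization). Camera on the embryonic and neonatal list gave an adjusted p of 0.403 (direction down), of 0.0321 after median-of-ratios scaling and of 0.00830 after quantile normalization. The embryonic and neonatal list had an adjusted p = 0.617 with an estimated correlation, and adjusted p = 0.263 with that and median-of-ratios scaling together. The member that rose was the joined locus of MYL6, a light chain of nonmuscle and smooth muscle myosin, and MYL6B, from 148 ± 40.4 to 447 ± 184 FPKM. The myosin-3 locus (LOC101113252, embryonic myosin, matched by its product description) fell from 732 ± 269 to 62.8 ± 35.0 FPKM (log2 change -3.68 ± 0.50 SE, adjusted p = 0.00201; SD, n = 3). MYH8 fell from 1642 ± 340.3 to 532 ± 184 FPKM. NES, nestin, fell from 123 ± 99.1 to 27.7 ± 13.3 FPKM, a call lost after median-of-ratios scaling (adjusted p = 0.0908). With a library left out, the call was lost for NES (adjusted p = 0.0573 without D135 replicate 1, 0.0704 without D135 replicate 2). Of 26 sarcomere scaffold genes, 15 rose, 0 fell and 11 did not pass, against 18 that rose and 0 that fell adjusted over the list alone. The sarcomere scaffold list had a median 1.05 above that of all loci (camera adjusted p = 6.05e-19, and adjusted p = 0.0156 with an estimated correlation). ACTA1 of that list rose from 1342 ± 422 to 5292 ± 1153 FPKM.

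**Figure D2:**
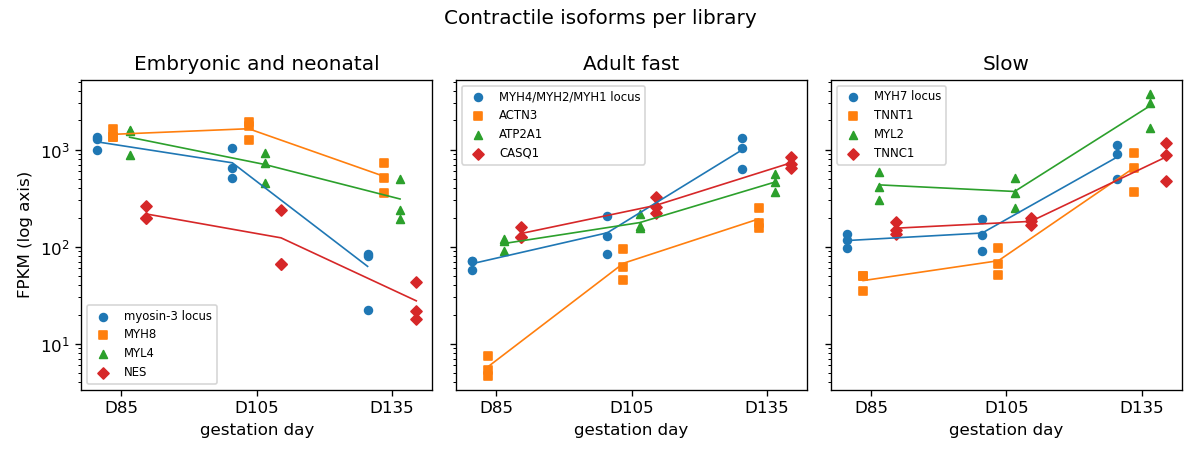
FPKM of 12 contractile loci in each library (points, log axis) by gestation day, with lines through the means of the 3 libraries per day. The myosin-3 locus goes from a mean of 1203 FPKM at D85 to 62.8 at D135, and the MYH4/MYH2/MYH1 locus from 66.9 to 1000.2.

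Many energy metabolism genes rose over the same interval. Of 46 oxidative phosphorylation genes, 36 rose, 0 fell and 10 did not pass, against 37 that rose and 0 that fell adjusted over the list alone. The oxidative phosphorylation list had a median 1.06 above that of all loci (camera adjusted p = 1.54e-37, and adjusted p = 0.0268 with an estimated correlation, or 0.0739 with that and median-of-ratios scaling together). Of 18 tricarboxylic acid cycle genes, 15 rose, 0 fell and 3 did not pass, against 15 that rose and 0 that fell adjusted over the list alone. The tricarboxylic acid cycle list had a median 0.95 above that of all loci (camera adjusted p = 6.70e-18, and adjusted p = 0.0156 with an estimated correlation). IDH2, mitochondrial isocitrate dehydrogenase, rose from 4.97 ± 0.700 to 15.8 ± 1.36 FPKM (SD, n = 3). Of 30 genes of fatty acid oxidation and uptake, 14 rose, 0 fell and 16 did not pass, against 15 that rose and 0 that fell adjusted over the list alone (23 rose and 0 fell after median-of-ratios scaling, 20 and 0 after quantile normalization). The fatty acid list had a median 0.82 above that of all loci (camera adjusted p = 6.70e-18, and adjusted p = 0.0268 with an estimated correlation). FABP3, a fatty acid carrier, rose from 23.1 ± 3.85 to 52.5 ± 0.573 FPKM. Of 30 genes of glycolysis and glycogen, 17 rose, 1 fell and 12 did not pass, against 19 that rose and 1 that fell adjusted over the list alone. The glycolysis list had a median 1.10 above that of all loci (camera adjusted p = 1.24e-17, and adjusted p = 0.0156 with an estimated correlation). GAPDH rose from 991 ± 87.5 to 3363 ± 981 FPKM. Of 9 phosphagen and myoglobin genes, 6 rose, 1 fell and 2 did not pass, against 7 that rose and 1 that fell adjusted over the list alone (8 rose and 0 fell after median-of-ratios scaling, 7 and 0 after quantile normalization). The phosphagen list had a median 1.42 above that of all loci (camera adjusted p = 6.10e-08, and adjusted p = 0.0156 with an estimated correlation). CKM, muscle creatine kinase, rose from 1033 ± 77.1 to 3501 ± 247 FPKM. MB, myoglobin, rose from 22.8 ± 15.1 to 183 ± 96.7 FPKM. Of 20 genes of excitation-contraction coupling, 4 rose, 0 fell and 16 did not pass, against 3 that rose and 0 that fell adjusted over the list alone (14 rose and 0 fell after median-of-ratios scaling, 7 and 0 after quantile normalization). The excitation-contraction coupling list had a median 0.77 above that of all loci (camera adjusted p = 3.28e-10, and adjusted p = 0.0251 with an estimated correlation). STRIT1, a peptide activator of the SERCA calcium pump, rose by a log2 change of 3.54. PPP1R3C, a glycogen-targeting phosphatase subunit, rose by 3.37.

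Most cell cycle genes fell from D105 to D135, and more imprinted and matrix genes fell than rose. Of all 13086 tested loci 4579 fell and 585 rose, so more falls than rises are not particular to these lists. Of 44 cell cycle genes, 0 rose, 43 fell and 1 did not pass, against 0 that rose and 43 that fell adjusted over the list alone. The cell cycle list had a median of -0.88 relative to all loci (camera adjusted p = 2.33e-16, and adjusted p = 0.137 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, fell from 24.1 ± 1.48 to 5.54 ± 1.46 FPKM (log2 change -1.96 ± 0.16 SE, adjusted p = 0.000622; SD, n = 3). MKI67 and CENPF fell by 1.66 and 1.76 on the log2 scale. Of 17 imprinted genes, 0 rose, 12 fell and 5 did not pass, against 0 that rose and 13 that fell adjusted over the list alone. The imprinted list had a median of -0.77 relative to all loci (camera adjusted p = 0.000706, and adjusted p = 0.0370 with an estimated correlation). PEG10 fell from 193 ± 11.2 to 26.2 ± 5.13 FPKM, and NNAT, neuronatin, from 23.7 ± 8.23 to 2.44 ± 0.894 FPKM. MEST fell from 17.7 ± 5.59 to 2.53 ± 0.561 FPKM. Of 41 matrix genes, 0 rose, 18 fell and 23 did not pass, against 0 that rose and 19 that fell adjusted over the list alone (1 rose and 7 fell after median-of-ratios scaling, 0 and 12 after quantile normalization). The matrix list had a median of -0.33 relative to all loci (camera adjusted p = 0.0388, and adjusted p = 0.677 with an estimated correlation). That median was -0.14 without D105 replicate 2 and -0.21 without D135 replicate 1. POSTN, periostin, fell from 91.4 ± 27.1 to 8.01 ± 2.61 FPKM and VCAN, versican, from 46.7 ± 7.19 to 5.83 ± 0.922 FPKM. The camera call of the matrix list was lost with a library left out (adjusted p = 0.0532 without D85 replicate 2, 0.0594 without D85 replicate 3, 0.261 without D105 replicate 2, 0.230 without D135 replicate 1 and 0.101 without D135 replicate 2), and the high COL1A1 of D105 replicate 2 belongs to this list. PRR32 fell from 33.8 ± 15.5 to 1.60 ± 1.39 FPKM.

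Among 16 myogenic regulators compared between D105 and D135, 0 rose, 8 fell and 8 did not pass, against 0 that rose and 8 that fell adjusted over the list alone (1 rose and 5 fell after median-of-ratios scaling, 0 and 6 after quantile normalization). Camera on the myogenic list gave an adjusted p of 0.327 (direction down), of 0.0568 after median-of-ratios scaling and of 0.0876 after quantile normalization. Over all 13086 tested loci, 585 rose and 4579 fell. MSC, musculin, fell from 19.3 ± 7.01 to 2.60 ± 0.989 FPKM, and CDH15, M-cadherin, from 11.4 ± 4.79 to 2.87 ± 0.290 FPKM (SD, n = 3). MSTN, myostatin, and MYOD1 fell by 1.45 and 0.60 on the log2 scale. Their adjusted p was 0.00912 and 0.0418, and 0.0579 and 0.505 after median-of-ratios scaling. Of 18 genes of the insulin-like growth factor axis, 0 rose, 10 fell and 8 did not pass, against 0 that rose and 10 that fell adjusted over the list alone (2 rose and 3 fell after median-of-ratios scaling, 1 and 3 after quantile normalization). Camera on the growth factor list gave an adjusted p of 0.240 (direction down), of 0.0632 after median-of-ratios scaling and of 0.0476 after quantile normalization. The growth factor list had an adjusted p = 0.487 with an estimated correlation, and adjusted p = 0.240 with that and median-of-ratios scaling together. IGF2 fell from 49.8 ± 21.5 to 13.4 ± 0.131 FPKM (adjusted p = 0.0191, and 0.0768 after median-of-ratios scaling). IGFBP2 fell from 16.5 ± 1.39 to 3.88 ± 1.16 FPKM, and the joined locus of IGF2R from 54.2 ± 7.30 to 24.5 ± 0.700 FPKM. With a library left out, calls were lost for MYOD1 (in 6 fits, up to adjusted p = 0.121 without D105 replicate 3) and IGF2 (adjusted p = 0.0545 without D135 replicate 2, 0.0567 without D105 replicate 1, 0.0579 without D105 replicate 2).

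Limma called 5164 loci between D135 and D105, 585 higher and 4579 lower, and 6097 between D135 and D85, 903 higher and 5194 lower. After median-of-ratios scaling the calls against D105 were 1389 higher and 911 lower, and against D85 1952 higher and 1642 lower. After quantile normalization they were 986 higher and 1072 lower, and 1599 higher and 1943 lower. Camera called 21 and 21 lists with the preset correlation, and 12 and 13 with an estimated correlation. With an estimated correlation and median-of-ratios scaling together it called 8 and 0. Of the lists called against D105 with an estimated correlation, the slow, adult fast, oxidative phosphorylation and hypoxia lists were lost with that scaling added.

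Over the whole span from D85 to D135, EEF1A2 reached 608 ± 45.4 FPKM (log2 change 6.61 ± 0.36 SE, adjusted p = 8.24e-05; SD, n = 3) and ACTN3 193 ± 48.9 FPKM (log2 change 4.82 ± 0.29 SE, adjusted p = 9.17e-05). Over all 13086 tested loci, 903 rose and 5194 fell across this span. The joined adult fast myosin locus rose from 66.9 ± 7.92 to 1000.2 ± 344 FPKM. The MYH7 locus, slow myosin joined with a neighbouring copy, rose from 116 ± 18.7 to 841 ± 320.2 FPKM. TNNT1 rose by a log2 change of 3.74, and ANKRD2, a stretch-responsive ankyrin repeat protein, by 3.74. AQP7, an aquaglyceroporin, and TMEM52 rose by 4.03 and 3.86. In the adult fast list 11 rose, 0 fell and 2 did not pass, against 11 that rose and 0 that fell adjusted over the list alone. The adult fast list had a median 1.57 above that of all loci (camera adjusted p = 2.88e-13, and adjusted p = 0.0349 with an estimated correlation, or 0.0953 with that and median-of-ratios scaling together). In the slow list 11 rose, 0 fell and 3 did not pass, against 11 that rose and 0 that fell adjusted over the list alone. The slow list had a median 1.82 above that of all loci (camera adjusted p = 1.29e-12, and adjusted p = 0.0441 with an estimated correlation, or 0.0860 with that and median-of-ratios scaling together). The myosin-3 locus fell from 1203 ± 192 to 62.8 ± 35.0 FPKM (log2 change -4.44 ± 0.50 SE, adjusted p = 0.000472), and MYL4, the embryonic and atrial light chain, from 1342 ± 404 to 310.3 ± 167 FPKM. In their list 1 rose, 8 fell and 1 did not pass, against 1 that rose and 8 that fell adjusted over the list alone, the riser again being the MYL6/MYL6B locus (log2 change 1.93). Camera on the embryonic and neonatal list gave an adjusted p of 0.140 (direction down), of 0.00691 after median-of-ratios scaling and of 0.00251 after quantile normalization. The embryonic and neonatal list had an adjusted p = 0.404 with an estimated correlation, and adjusted p = 0.191 with that and median-of-ratios scaling together. PAX7, the satellite cell regulator, fell from 2.82 ± 0.789 to 0.518 ± 0.0618 FPKM. TMEM8C, the myoblast fusion protein myomaker, fell from 7.49 ± 0.589 to 0.862 ± 0.167 FPKM. MSC and CDH15 fell by 3.19 and 2.21 on the log2 scale. Of 16 myogenic regulators, 0 rose, 10 fell and 6 did not pass, against 0 that rose and 10 that fell adjusted over the list alone (1 rose and 5 fell after median-of-ratios scaling, 1 and 6 after quantile normalization). Camera on the myogenic list gave an adjusted p of 0.137 (direction down), of 0.0216 after median-of-ratios scaling and of 0.0359 after quantile normalization. The myogenic list had an adjusted p = 0.543 with an estimated correlation, and adjusted p = 0.412 with that and median-of-ratios scaling together. Of 14 satellite cell markers, 0 rose, 8 fell and 6 did not pass, against 0 that rose and 8 that fell adjusted over the list alone (1 rose and 6 fell after median-of-ratios scaling, 1 and 6 after quantile normalization). Camera on the satellite cell list gave an adjusted p of 0.279 (direction down), of 0.0410 after median-of-ratios scaling and of 0.0466 after quantile normalization. The satellite cell list had an adjusted p = 0.516 with an estimated correlation, and adjusted p = 0.212 with that and median-of-ratios scaling together. CALCR, the calcitonin receptor, and FGFR4, a fibroblast growth factor receptor, fell by 1.78 and 1.58 on the log2 scale.

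Many metabolic genes rose from D85 to D135 as well. In oxidative phosphorylation 38 rose, 0 fell and 8 did not pass, against 39 that rose and 0 that fell adjusted over the list alone. The oxidative phosphorylation list had a median 1.13 above that of all loci (camera adjusted p = 4.29e-31, and adjusted p = 0.0349 with an estimated correlation, or 0.0860 with that and median-of-ratios scaling together). NDUFS7, a complex I subunit, rose from 10.3 ± 1.40 to 28.1 ± 5.28 FPKM (SD, n = 3). In the tricarboxylic acid cycle 15 rose, 0 fell and 3 did not pass, against 15 that rose and 0 that fell adjusted over the list alone. The tricarboxylic acid cycle list had a median 1.09 above that of all loci (camera adjusted p = 5.08e-15, and adjusted p = 0.0285 with an estimated correlation, or 0.0559 with that and median-of-ratios scaling together). IDH2 rose by a log2 change of 1.84. In glycolysis and glycogen 19 rose, 2 fell and 9 did not pass, against 19 that rose and 2 that fell adjusted over the list alone. The glycolysis list had a median 1.23 above that of all loci (camera adjusted p = 1.61e-16, and adjusted p = 0.0285 with an estimated correlation, or 0.0559 with that and median-of-ratios scaling together). PGAM2, muscle phosphoglycerate mutase, rose from 145 ± 12.1 to 885 ± 249 FPKM. FBP2, muscle fructose bisphosphatase, rose from 2.49 ± 0.700 to 28.4 ± 9.11 FPKM. In the phosphagen and myoglobin list 5 rose, 1 fell and 3 did not pass, against 7 that rose and 1 that fell adjusted over the list alone. The phosphagen list had a median 1.37 above that of all loci (camera adjusted p = 5.31e-06, and adjusted p = 0.0285 with an estimated correlation, or 0.0559 with that and median-of-ratios scaling together). CKM and MB rose by log2 changes of 2.50 and 3.36, and CKB, brain-type creatine kinase, fell by 1.75 on the log2 scale. Of 25 glucocorticoid-responsive genes, 10 rose, 1 fell and 14 did not pass, against 10 that rose and 1 that fell adjusted over the list alone. The glucocorticoid list had a median 0.75 above that of all loci (camera adjusted p = 1.38e-08, and adjusted p = 0.0312 with an estimated correlation, or 0.0559 with that and median-of-ratios scaling together). ZBTB16, a transcription factor, rose from 0.168 ± 0.0354 to 3.40 ± 0.386 FPKM, and TXNIP, a thioredoxin-binding protein, from 20.5 ± 2.79 to 62.2 ± 3.64 FPKM. In the thyroid hormone axis 5 rose, 1 fell and 4 did not pass, against 5 that rose and 1 that fell adjusted over the list alone (5 rose and 0 fell after median-of-ratios scaling, 5 and 0 after quantile normalization). The thyroid list had a median 1.21 above that of all loci (camera adjusted p = 0.000237, and adjusted p = 0.0385 with an estimated correlation, or 0.0666 with that and median-of-ratios scaling together). ATP2A1, the fast-fibre calcium pump, and SLC2A4, the insulin-responsive glucose carrier, rose by log2 changes of 2.08 and 1.66. In the hypoxia list 6 rose, 3 fell and 6 did not pass, against 6 that rose and 3 that fell adjusted over the list alone (9 rose and 1 fell after median-of-ratios scaling, 8 and 1 after quantile normalization). The hypoxia list had a median 0.68 above that of all loci (camera adjusted p = 0.000351, and adjusted p = 0.0349 with an estimated correlation, or 0.0758 with that and median-of-ratios scaling together). LDHA, lactate dehydrogenase A, and VEGFA, a vascular growth factor, rose by 1.63 and 1.47, and ADM, adrenomedullin, fell by 1.01 on the log2 scale.

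**Figure D3:**
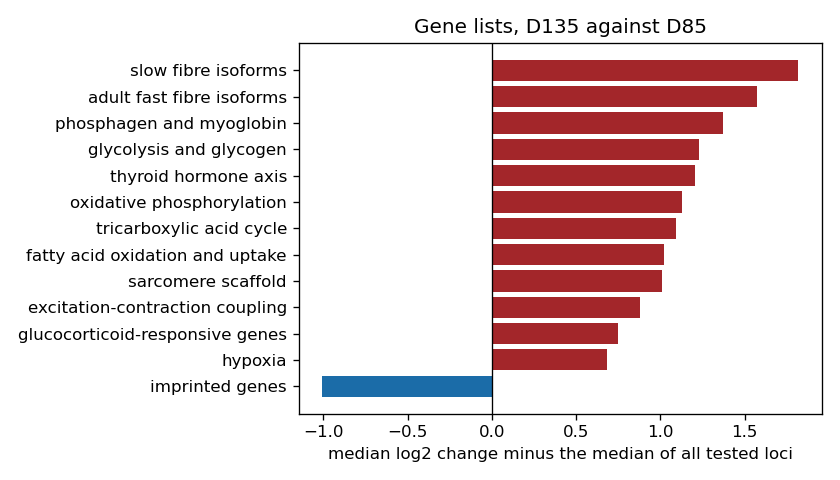
Median log2 change from D85 to D135 of each gene list that camera called with the preset and with an estimated correlation, less the median of all tested loci (horizontal axis, log2). Imprinted genes lie at -1.0 and slow fibre isoforms at 1.82. None of these lists passes with an estimated correlation after median-of-ratios scaling, and their medians keep their signs under that scaling.

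Cell cycle genes fell from D85 to D135, where 0 rose, 44 fell and 0 did not pass, against 0 that rose and 44 that fell adjusted over the list alone. The cell cycle list had a median of -1.15 relative to all loci (camera adjusted p = 3.54e-15, and adjusted p = 0.143 with an estimated correlation). TOP2A fell from 26.9 ± 2.89 to 5.54 ± 1.46 FPKM and RRM2, ribonucleotide reductase, from 6.24 ± 0.898 to 0.984 ± 0.273 FPKM (SD, n = 3). In the imprinted list 0 rose, 14 fell and 3 did not pass, against 1 that rose and 14 that fell adjusted over the list alone. The imprinted list had a median of -1.0 relative to all loci (camera adjusted p = 0.00160, and adjusted p = 0.0441 with an estimated correlation, or 0.0559 with that and median-of-ratios scaling together). PEG10 fell from 357 ± 58.1 to 26.2 ± 5.13 FPKM, and DLK1, an inhibitor of adipocyte differentiation, from 82.5 ± 31.1 to 12.7 ± 0.0614 FPKM. NNAT fell by 3.82 on the log2 scale. IGF2 fell from 74.3 ± 39.4 to 13.4 ± 0.131 FPKM, while IGFBP3, a carrier of insulin-like growth factors, rose from 10.6 ± 2.71 to 19.9 ± 3.50 FPKM. In that axis 2 rose, 9 fell and 7 did not pass, against 2 that rose and 10 that fell adjusted over the list alone (3 rose and 7 fell after median-of-ratios scaling, 2 and 6 after quantile normalization). Camera on the growth factor list gave an adjusted p of 0.421 (direction down), of 0.148 after median-of-ratios scaling and of 0.165 after quantile normalization. BCAT1, a branched-chain aminotransferase, fell from 15.6 ± 4.07 to 0.572 ± 0.299 FPKM and PRR32 from 58.0 ± 6.38 to 1.60 ± 1.39 FPKM.

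Matrix genes went both ways from D85 to D135, where 3 rose, 15 fell and 23 did not pass, against 3 that rose and 15 that fell adjusted over the list alone (7 rose and 9 fell after median-of-ratios scaling, 3 and 12 after quantile normalization). Camera on the matrix list gave an adjusted p of 0.754 (direction down), of 0.432 after median-of-ratios scaling and of 0.0191 after quantile normalization. The matrix list had an adjusted p = 0.971 with an estimated correlation, and adjusted p = 0.864 with that and median-of-ratios scaling together. Their median log2 change of -0.46 turned to 0.00194 after median-of-ratios scaling and to -0.31 after quantile normalization. ELN, elastin, rose from 3.64 ± 1.34 to 36.9 ± 28.8 FPKM (SD, n = 3). POSTN and VCAN fell by 3.88 and 3.31 on the log2 scale. In the endothelial list 5 rose, 0 fell and 11 did not pass, against 5 that rose and 0 that fell adjusted over the list alone (11 rose and 0 fell after median-of-ratios scaling, 9 and 0 after quantile normalization). The endothelial list had a median 0.55 above that of all loci (camera adjusted p = 5.49e-06, and adjusted p = 0.0921 with an estimated correlation). ESAM, an endothelial adhesion protein, and VWF, von Willebrand factor, rose by log2 changes of 0.69 and 0.65. In the adipocyte list 4 rose, 0 fell and 8 did not pass, against 3 that rose and 0 that fell adjusted over the list alone. The adipocyte list had a median 1.05 above that of all loci (camera adjusted p = 0.000298, and adjusted p = 0.365 with an estimated correlation). Without D135 replicate 2, 2 rose and the median was 0.76 above that of all loci (camera adjusted p = 0.00405). PLIN4, a lipid droplet protein, and CFD, adipsin, rose by 1.47 and 0.87.

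At several loci named by the size of their change, values jumped between libraries of the same day or were listed at 0, and values are given for replicates 1, 2 and 3. RPS15, a ribosomal protein gene, was at 1.0, 1.30 and 0.805 FPKM at D85, 199, 0.556 and 1.09 at D105 and 495, 594 and 486 at D135. HSPB2, a small heat shock protein gene, was at 0.000237, 0.000715 and 6.48 FPKM at D85, 0.000886, 43.6 and 0.000701 at D105 and 42.8, 34.1 and 32.7 at D135. NCAPD2, a condensin subunit, was at 72.8, 9.03 and 62.0 FPKM at D85, 5.26, 47.3 and 68.2 at D105 and 2.38, 2.53 and 2.54 at D135. C4H7orf55 was at 20.4, 15.6 and 12.3 FPKM at D85, 0.0888, 0.102 and 6.87 at D105 and 22.3, 29.0 and 22.1 at D135. A further RPL10 locus was listed at 0 in every D85 library, at 0, 0 and 34.7 FPKM at D105 and at 34.0, 38.1 and 33.6 at D135. With a library left out, calls were lost for RPS15 (in 5 fits, up to adjusted p = 0.0668 without D105 replicate 3) and NCAPD2 (in 7 fits, up to adjusted p = 0.133 without D105 replicate 3) against D105, and HSPB2 (in 5 fits, up to adjusted p = 0.122 without D85 replicate 2) and NCAPD2 (in 5 fits, up to adjusted p = 0.0826 without D85 replicate 1) against D85. Loci named UCKL1, RNF220, EMC10, HIVEP2, EIF4B, GATAD2B, NIPBL, FBXL7, JOSD1 and ANK2 held no reference transcript, and another locus of the same name held the annotated gene. The RNF220 fragment was at 5.40, 4.70 and 6.50 FPKM at D85, listed at 0 in every D105 library, and at 3.94, 4.95 and 4.17 at D135. Annotated RNF220, a ubiquitin ligase, was at 8.03 ± 0.419, 7.34 ± 0.970 and 5.22 ± 0.591 FPKM (SD, n = 3). The EIF4B fragment was listed at 0 in every D85 and D105 library and at 9.0, 8.52 and 4.72 FPKM at D135. Annotated EIF4B, an initiation factor, was at 103 ± 12.1, 105 ± 11.7 and 109 ± 12.7 FPKM.

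D105 was also set against the mean of D85 and D135, which asks whether the change from D85 to D105 equals that from D105 to D135. These intervals are of 20 and 30 days, so a gene that changes at a constant rate per day also departs from that mean. The median locus differed by 0.16 on the log2 scale, and by -0.01 after median-of-ratios scaling. A call here does not show that D105 differed from D85. Higher at D105 than the mean of the other days was a joined locus of the microRNA genes MIR495 and MIR377. It was at 15.9 ± 1.74, 22.6 ± 3.09 and 3.18 ± 1.30 FPKM at D85, D105 and D135 (SD, n = 3). RMI2 was at 0.758 ± 0.142, 4.14 ± 1.01 and 1.32 ± 0.382 FPKM, and RAP2C, a small GTPase, at 3.41 ± 0.198, 8.05 ± 1.58 and 2.03 ± 0.304 FPKM. TSPAN33, a tetraspanin, and MT3, a metallothionein, were higher by log2 differences of 1.10 and 0.95. For TSPAN33, MT3 and the MIR495 locus the adjusted p was 0.0650 after median-of-ratios scaling. PRSS23 was lower at D105, with 1.18 ± 0.264, 0.0773 ± 0.0846 and 2.33 ± 0.337 FPKM. The phosphatase gene DUPD1 was lower than the mean of the other days too, with 1.58 ± 0.158, 1.09 ± 0.147 and 7.06 ± 1.37 FPKM. Limma called 46 loci, 36 higher and 10 lower, and 5658 differed between any of the days by the moderated F test (3726 without D135 replicate 2). The split was 5 higher and 10 lower after median-of-ratios scaling, 12 higher and 11 lower after quantile normalization and 20 higher and 10 lower with totals taken without the top 50 loci. It was 4 higher and 12 lower without D105 replicate 1 and 7 higher and 10 lower without D105 replicate 3. The count went from 9 without D135 replicate 2 to 69 without D105 replicate 2. With a library left out, calls were lost for MIR495/MIR377 (in 7 fits, up to adjusted p = 0.128 without D105 replicate 1), RMI2 (adjusted p = 0.0532 without D85 replicate 1, 0.0658 without D105 replicate 1, 0.0662 without D135 replicate 2), TSPAN33 (in 9 fits, up to adjusted p = 0.123 without D105 replicate 1), MT3 (in 9 fits, up to adjusted p = 0.135 without D105 replicate 3) and DUPD1 (adjusted p = 0.0615 without D105 replicate 3, 0.0631 without D135 replicate 2, 0.0658 without D105 replicate 1).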

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

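The tests of loci without a reference transcript, of doubtful zeros, of members matched by description and of an estimated correlation with median-of-ratios scaling were chosen after the results were seen. Of 2965 values of named genes under alternatives, 2752 kept their direction and side of the threshold, 213 lost the call, 0 gained it and 0 reversed. At least 115 of the 131 named results were calls in the main fit, so few could gain a call. Many were named for the size of their change, so these shares do not hold for other loci. The causes were not tested. Without a filter D105 against D85 gave 45 loci (21 higher and 24 lower), with FPKM of at least 5 it gave 12, and with only its 2 days fitted 17. With FPKM of at least 5, where fewer loci are tested, the counts were 3271 for D135 against D105, 3715 for D135 against D85 and 3463 for any day. Median-of-ratios scaling gave 2300 for D135 against D105, 3594 for D135 against D85 and 2993 for any day, and 15 for D105 against the mean of the other days. Quantile normalization gave 2058 for D135 against D105, 3542 for D135 against D85 and 2845 for any day, and 23 for that last contrast. The last contrast gave 30 with totals without the top 50 loci, 164 with library weights and 78 over loci with a reference transcript. With an estimated correlation camera called 0, 12 and 13 lists for D105 against D85, D135 against D105 and D135 against D85, and 0, 8 and 0 with median-of-ratios scaling as well. The mean r within days was 0.827 with a pseudocount of 0.1 and 0.468 over the 500 most variable loci. With each library left out in turn, the counts of loci ranged from 14 to 28 for D105 against D85, 3456 to 5092 for D135 against D105, 4735 to 6152 for D135 against D85, 3726 to 5409 for any day (lowest without D135 replicate 2) and 9 to 69 for D105 against the mean. Lists ranged from 15 to 23, 18 to 21 and 18 to 23 in the order of those pairs. Without D105 replicate 2, which stood apart, the pairs gave 22, 4317 and 6152 loci. The last contrast gave 20 loci without D85 replicate 1, 29 without D85 replicate 3, 16 without D105 replicate 1, 17 without D105 replicate 3, 9 without D135 replicate 2 and 69 without D105 replicate 2. D105 against D85 gave 14 without D135 replicate 2, 16 without D85 replicate 2 or D85 replicate 3, with 15 lists without D85 replicate 2 or D105 replicate 2 and 16 without D85 replicate 3. Leaving out a library leaves 2 in its day. Relative depth was highest at D135, and absolute depth is unknown, so no detection limit is given.

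The labels give each day replicates 1 to 3. Same-numbered libraries did not deviate together: r of their deviations from the day means ranged from -0.066 to 0.06, and 3 of 9 libraries had their highest r with a library of their own number. With a replicate block the counts were 8 for D105 against D85, 4320 for D135 against D105, 5495 for D135 against D85 and 4600 for any day, and 3 for D105 against the mean of D85 and D135. Camera called 23, 19 and 22 lists with the block.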

Other observations

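The tests of explanations, the counts over other splits, and the histones, globins and paralog pairs in this part were chosen after the results were seen. Of 38 histone loci tested, 0 rose, 17 fell and 21 did not pass at D135 against D105, and 0 rose, 20 fell and 18 did not pass against D85. Their median log2 changes were -1.07 and -1.56, against -0.33 and -0.35 for all tested loci, of which 4579 and 5194 of 13086 fell. No test set them against other loci. After median-of-ratios scaling 14 and 18 fell. EEF1A1, the widely expressed elongation factor, fell from 906 ± 157 FPKM at D85 to 447 ± 65.6 at D135 (SD, n = 3; limma adjusted p = 0.00199, and 0.0666 after median-of-ratios scaling) while its muscle paralog EEF1A2 rose from 5.61 ± 2.85 to 608 ± 45.4. RPL3 fell from 594 ± 3.43 to 255 ± 24.5 FPKM (limma adjusted p = 0.000249) as RPL3L, its muscle paralog, rose from 2.63 ± 0.927 to 49.5 ± 9.23. Among 22 translation factors 1 rose, 9 fell and 12 did not pass, against 1 that rose and 9 that fell adjusted over the list alone (4 rose and 1 fell after median-of-ratios scaling, 1 and 4 after quantile normalization), and among 70 cytosolic ribosomal protein genes 1 rose, 12 fell and 57 did not pass, against 1 that rose and 2 that fell adjusted over the list alone (20 rose and 1 fell after median-of-ratios scaling, 2 and 24 after quantile normalization). The medians of these lists, -0.29 and -0.15, turned to 0.18 and 0.32 after median-of-ratios scaling and to -0.13 and -0.29 after quantile normalization. Relative to all loci they were 0.06 and 0.20, with camera's direction down for the first, against its median, and up for the second. Camera on the translation factors gave adjusted p = 0.786, 0.164 after median-of-ratios scaling and 0.328 after quantile normalization. For the ribosomal proteins it gave adjusted p = 0.255, 4.96e-06 (direction up) after median-of-ratios scaling and 5.81e-05 (direction down) after quantile normalization, so the direction of this list depends on the scaling. With an estimated correlation its adjusted p = 0.868, and 0.469 with median-of-ratios scaling as well. RPS15, a ribosomal protein gene whose values jumped between D105 libraries, rose from D85 to D135 (limma adjusted p = 0.0051).

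In 24 changes at 22 loci with a symbol, every library of a day was at 2 FPKM or more and every library of another day at 2% of that or less. At 16 of these loci no reference transcript is held. A candidate explanation is that such loci are assembled pieces that took a gene's name. The annotated loci of those names had a median absolute log2 change of 0.291, against 2.91 at the fragments. The explanation needs such a low value, but the fragments were picked for their large change, so 2.91 follows from the choice. The annotated loci could also stay near 0.291 if the fragments changed for another reason, so this comparison does not decide. The explanation leaves annotated loci such as EEF1A2 and TMEM52 aside, and no biological explanation was tested.

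The median locus was lower at D135, with a log2 change from D85 of -0.35. Loci at FPKM 5 or more gave -0.38, which argues against lost low values as the whole cause. Scaling to totals without the 50 loci of highest FPKM left -0.26. Those totals are sums of FPKM, not of mapped fragments, so they do not decide whether the top loci took more of the fragments. Another composition of the RNA with gestation day may lie behind the lower median. It cannot be told apart from the scaling, since the table holds no spike-in or RNA yield.

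Adult beta-globin was at 1.15 ± 0.848, 13.3 ± 5.77 and 95.6 ± 39.8 FPKM at D85, D105 and D135 and fetal beta-globin at 160.1 ± 57.0, 126 ± 17.0 and 62.6 ± 17.5 (SD, n = 3; limma adjusted p = 0.000160 and 0.00667 for D135 against D85). More blood in the D135 muscle would raise both, but the fetal locus had a log2 change of -1.32, which argues against it as the whole cause. Reads shared between the copies would move both loci together, but their log2 changes differ by 6.81. Near-identical globin copies leave the split of reads uncertain, and alpha-globin was at 83.1 ± 18.2, 194 ± 73.0 and 77.9 ± 23.9 FPKM. A switch from fetal to adult haemoglobin with gestation day stays a hypothesis that was not tested.

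COL1A2 in D105 replicate 2 was at 2670.2 FPKM, against 636 and 658 in the other D105 libraries. The counts were set against other splits of the same libraries. Between 2 days there are 10 splits, too few for a share under 0.05: the real counts of loci were 26, 5164 and 6097 for D105 against D85, D135 against D105 and D135 against D85, with the highest other splits at 10, 14 and 7, and 1 split as large in each. For lists the real counts were 25, 21 and 21, the highest others 14, 22 and 21, and 1, 2 and 2 splits were as large. For any day, 1 of 100 splits of the 9 libraries, the real split, gave 5658 loci or more (highest other 5034). That share is under 0.05, but it would exclude chance only for independent libraries. The count asks about any day and another split came near it, so the share does not show that all 3 days differ. The labels do not say that the libraries came from separate fetuses, so chance between fetuses is not excluded. For D105 against the mean of D85 and D135, 2 of 100 splits gave 46 or more, the other giving 6277, which points to a structure of the libraries. Splits that part the D135 libraries gave at most 11, and only 3 of the 100 keep them together, so these splits do not bear on D105. With the D135 group kept there are 20 splits, too few for a share under 0.05: 16 gave 46 or more, the real one included, and the highest other gave 3414. A split that mixes D85 and D105 libraries can bring part of the D135 change into this contrast, as the real split can. How much of the counts comes from this was not tested, so these splits do not bear on D105 either.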
